A study of Caenorhabditis elegans with 24 samples.

How the data were processed

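Small RNA was sequenced from embryos of Caenorhabditis elegans wild-type strain N2 at 8 stages of embryogenesis. Per the labels, embryos were dissected out of adults, collected by mouth pipette and timed in minutes after the 4-cell stage, with 50 embryos in each sample and 3 samples at each time. The first times were 60, 120, 180 and 225 min, and the later ones 270, 330, 410 and 500 min. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq small RNA kit, for which no molecular identifiers are described. The replicate numbers are those of the labels, and nothing in the labels says that a number marks a shared batch or day, or that the 3 samples of a stage came from separate cultures. The p-values therefore measure only the spread between these samples, part of which may be technical.

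The authors deposited 1 table of raw read counts, whole numbers that were not normalized, for 434 mature miRNA arms in 24 libraries. Per the submitters' processing notes, Bowtie and HTSeq were used; their versions, the genome build, the miRNA annotation, the treatment of reads that map to more than 1 place and the use of strand are not given in the sources used here. Members of a miRNA family that are nearly identical in sequence could share reads. In this respect values of single members of the mir-35, mir-51, mir-58, mir-2, mir-44 and mir-64 groups are less certain than the sums over their family. These sums take in both arms of each hairpin, and they lack arms that received almost no reads, such as miR-80-3p. Arms carry the 5p and 3p names of the table. Of the 434 arms, 297 had at least 1 read. Total counts ran from 88,482 in 225 min replicate 2 to 1,594,151 in 410 min replicate 3, an 18.02-fold range, so the shallow libraries give the least precise values. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

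Counts were analysed in R 4.3.3 with edgeR 4.0.16. Arms were kept by filterByExpr with the stage as the group and a minimum count of 10, which left 128. Libraries were scaled by TMM factors, dispersions were estimated robustly over all 24 libraries with the stage as a factor, and stages were compared with the quasi-likelihood F-test; the common biological coefficient of variation was 0.706. The first test asked whether a miRNA differed among the 8 stages, the second compared 500 min with 60 min, and 7 more compared neighbouring stages. Adjusted p-values are Benjamini-Hochberg values over the 128 miRNAs of each test, with a threshold of 0.05. An adjusted p of a single miRNA comes from this edgeR test unless another setting, such as DESeq2 or a left-out library, is named with it. Under another setting the adjustment covers the miRNAs tested there. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM over TMM-scaled library sizes, given as mean ± SD over the 3 libraries of a stage. Shares are percentages of all counts in a library. They do not depend on scaling factors, but a share also falls where other miRNAs take up more of the counts. Where all 3 libraries of 1 stage had no count, the fold is a lower bound against a floor of 3 counts over the 3 libraries; with 1 to 3 counts, the ratio is given with a 95% Poisson interval.

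The genes named in the text follow a rule fixed with the design, before the data were examined, as were the lists, the tests and the alternatives, except those said to be chosen afterwards. It takes the 10 miRNAs with the highest mean CPM; for 500 min against 60 min, the 12 largest rises and 12 largest falls past the threshold with no overlap between the libraries of the stages; for each neighbouring step, the 3 largest rises and falls on the same terms; and the members of 12 fixed lists. The lists were the mir-35 family, the mir-51 family, the heterochronic miRNAs of the lin-4 and let-7 families, the mir-58 (bantam) family, the mir-2 family, the mir-44 family, the mir-64 to mir-66 and mir-229 cluster, the mir-72 (miR-31) family, tissue-restricted miRNAs of muscle, neurons and intestine, miRNAs conserved among bilaterians, mirtrons, and miRNAs of the mother's somatic gonad. The last list, with the heterochronic miRNAs, served as a marker of maternal tissue. All lists name hairpins, so every tested arm of a listed hairpin counted, whichever arm defines its family. Lists with at least 3 tested arms were tested with fry of limma 3.58.1 on voom values, directionally, with Benjamini-Hochberg adjustment over the lists; fry asks whether the arms of a list move 1 way on balance and does not compare a list with other miRNAs. The shares of 3 lists were correlated with time over the 24 libraries by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples.

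The edgeR procedure was tested on simulated counts for the 128 miRNAs, with 40 of them changed by 4-fold or 16-fold, in 20 draws per comparison. At the depths of 500 min against 60 min it found 27.1% of 4-fold and 71.2% of 16-fold changes. It made 4.06 false calls per 100 calls there. At 330 min against 270 min it found 30.5% and 73.2%, with 2.46 false calls per 100. In the data, 80 of the 128 miRNAs were called at 500 min against 60 min, more than the 40 changed here. These rates therefore hold for the simulated changes. They do not cover a larger shift in composition, such as that of the most abundant miRNAs over the timecourse. A 16-fold fall of the mir-35 family was found by fry in 20 of 20 draws, while unchanged lists were called in 6 of 160 cases. An unchanged mir-35 share passed the permutation test in 1 of 20 draws. The same 10 miRNAs were raised 16-fold in the middle stages in each of the 20 draws. Of these 200 rises 97 were found, with 0 false calls, a rate that holds for those 10 miRNAs only.

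The alternatives were DESeq2 size factors in edgeR, total counts without factors, no low-count filter, DESeq2 1.42.0, the replicate number as a block, leaving out the 5 most abundant miRNAs, leaving out each replicate number and each library in turn, and fits on the 6 libraries of the stages compared. Leaving out each library with the filter and TMM factors of all 24 kept, leaving 60 min replicate 3 out of the share correlations, and the counts by stage of peak and for the middle stages were added after the data were seen. The share correlations were repeated without the most abundant miRNA outside the list in the denominator. Hairpin positions come from the Ensembl 115 annotation of build WBcel235, matched by hairpin name; 235 of the 242 hairpins in the table matched. They place the genes on that build and were not used for counting. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.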

Results

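The deposited table gives read counts of mature miRNAs in 24 libraries of C. elegans embryos. There were 3 libraries at each of 8 times from 60 to 500 min after the 4-cell stage. The libraries held 9,908,958 counts in all. Mean totals per stage ran from 199,111 at 60 min to 834,359 at 410 min (n = 3 each). Replicates of a stage had correlations of log2 CPM between 0.851 and 0.973, with a median of 0.947. In no pair did the counts look like 1 library deposited 2 times (chi-square of at least 38.6 per degree of freedom, a measure that separate samples and amplified reads both raise). The first principal component held 50.0% of the variance and the second 15.5%. The third, with 5.93%, set 60 min replicate 3 apart at a score of 18.03, while the other 23 libraries lay within 9.08 of 0.

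The 10 most abundant miRNAs took 81.4% ± 4.56 of the counts (SD, n = 24), and their order changed over the timecourse. miR-57-3p comes from a hairpin of the conserved miR-10 family. It made up 1.06% ± 0.199 of counts at 60 min and 25.4% ± 4.50 at 500 min (SD, n = 3 each). miR-228-5p went from 0.276% ± 0.208 to 16.2% ± 2.73. miR-82-3p went from 0.932% ± 0.599 to 12.2% ± 3.23 and miR-81-3p from 0.276% ± 0.347 to 5.72% ± 1.36. In the other direction, miR-64-5p went from 19.7% ± 3.42 to 2.70% ± 0.642, miR-65-5p from 13.9% ± 3.48 to 2.25% ± 0.559, miR-61-3p from 8.88% ± 1.199 to 1.36% ± 0.243 and miR-229-3p from 7.58% ± 2.20 to 0.560% ± 0.150. miR-72-5p was the largest single species at 60 min with 24.2% ± 1.31 and stood at 12.2% ± 1.12 at 500 min, and miR-44-5p went from 1.30% ± 0.145 to 3.03% ± 0.407. All 10 differed among the stages, with edgeR adjusted p from 4.18e-15 for miR-57-3p to 0.000278 for miR-44-5p. The order of abundance rests on which arms received reads in the table. Counts per hairpin had a rank correlation of -0.335 with position along the chromosome, and miR-80-3p, a sister of miR-81-3p and miR-82-3p, had 4 reads in all libraries together. In several hairpins 1 arm was nearly empty: miR-44-3p had 0 reads against 476034 for miR-44-5p, and miR-124-3p 17 against 300 for miR-124-5p. miR-34-5p had 17 against 746 for miR-34-3p. Reads lost or counted for the wrong arm were not tested for, so the arm that leads here need not be the main arm in embryos.

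**Figure D1:**
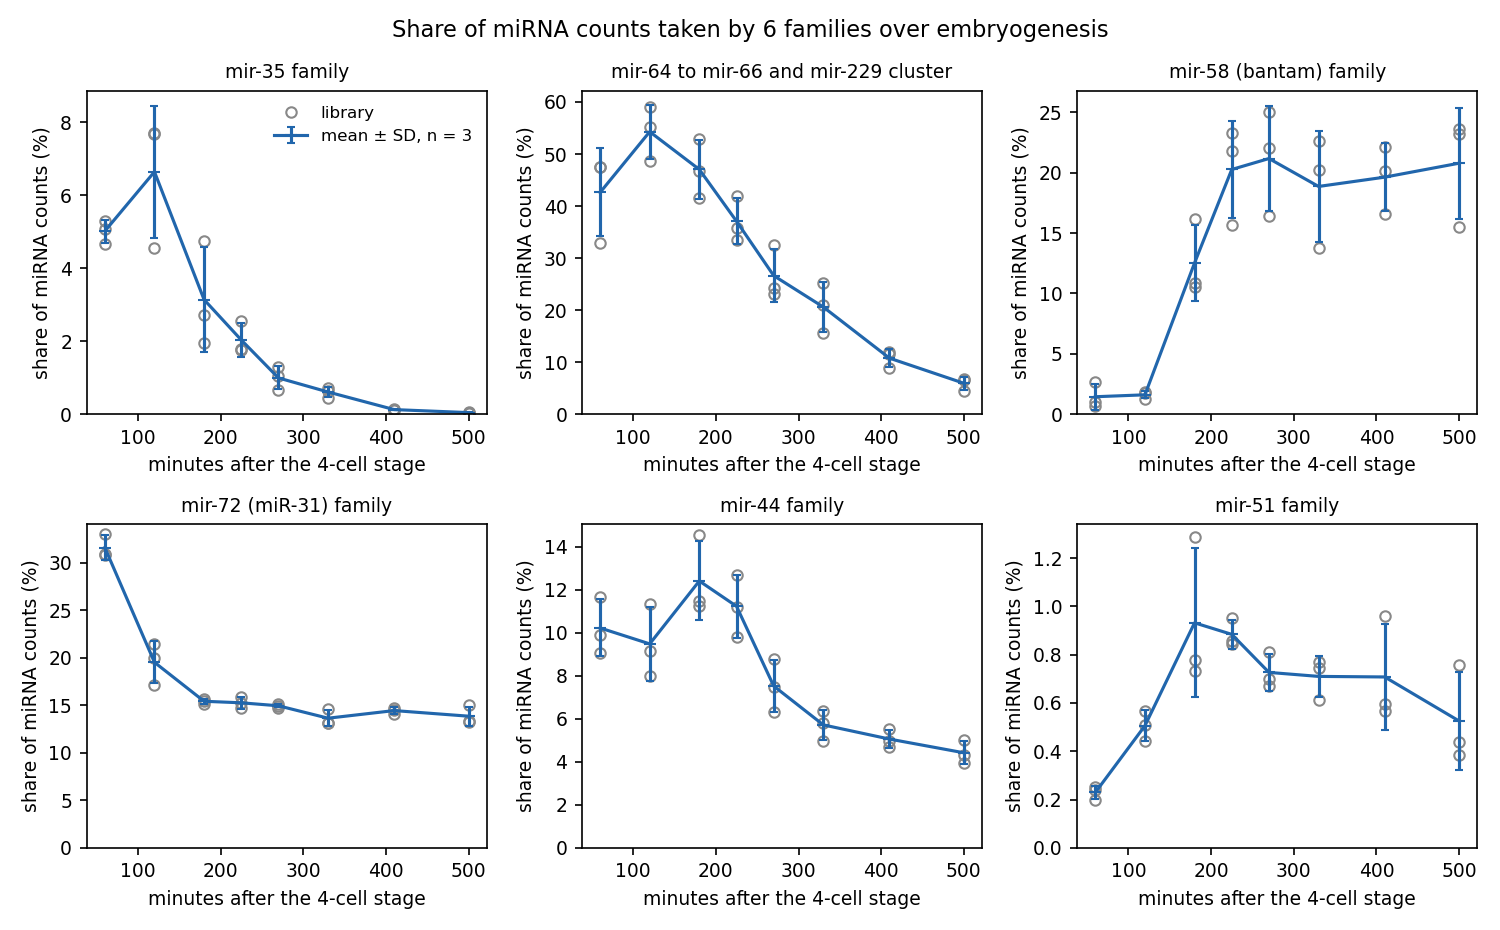
Share of all miRNA counts (percent, y axis) taken by fixed miRNA lists at each time after the 4-cell stage (minutes, x axis), with points for single libraries and lines and bars for the mean and SD of 3 libraries. The mir-64 to mir-66 and mir-229 cluster peaks at 54.3% at 120 min and ends at 5.97%, while the mir-58 family rises from 1.61% at 120 min to 12.5% at 180 min.

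Of the 128 miRNAs tested, 87 differed among the 8 stages (edgeR F-test, adjusted p under the threshold; 89 at an unadjusted p under 0.05). Early and late stages held most of their peaks. By mean TMM-scaled CPM, 29 of the 87 were highest at 60 min, among them miR-35-3p, miR-36-3p, miR-61-3p and miR-74-5p, and 37 were highest at 410 or 500 min, among them miR-57-3p, miR-228-5p, miR-81-3p and miR-242. The stages between held fewer, with 9 at 180 min (miR-44-5p, miR-43-3p and miR-52-5p among them), 6 at 330 min, 3 at 270 min (miR-45-3p, miR-67-3p and miR-229-5p), 2 at 120 min (miR-229-3p and miR-38-3p) and 1 at 225 min (miR-1-5p). The count at 60 min depended on scaling: it was 20 with DESeq2 size factors, 16 with total counts and 11 without 60 min replicate 1 with the filter and TMM factors computed anew, but 21 to 31 without any 1 library when these were kept.

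The comparison of the last with the first stage asked which miRNAs differed between the youngest and the oldest embryos sampled. At 500 min, 44 miRNAs were higher and 36 lower than at 60 min, 80 of 128 in all (85 at an unadjusted p under 0.05). Several of the risers had no read in any 60 min library. miR-242 reached 2049 ± 202 CPM at 500 min, at least 270.5-fold higher (edgeR adjusted p 2.78e-05). miR-790-3p was at least 129-fold higher, miR-788-3p at least 66.6-fold and miR-54-3p at least 41.0-fold. lsy-6-3p, of a miRNA that sets left-right asymmetry in a taste neuron pair, was at least 31.7-fold higher at 240 ± 103 CPM (edgeR adjusted p 0.000217). miR-228-3p, with 1 read at 60 min, had a ratio of 1701 (95% counting interval 305 to 67190), and miR-76-3p, with 3 reads, a ratio of 166 (56.6 to 806; fitted log2 fold change 7.09, and 12.00 without 60 min replicate 1). The other 5 of the 12 largest rises were miR-79-3p, miR-248, miR-83-3p, miR-790-5p and miR-124-5p, at least 22.8-fold, 20.4-fold, 13.7-fold, 12.1-fold and 9.80-fold higher.

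The largest falls were dominated by the mir-35 family. miR-39-5p went from 19722 ± 2849 CPM to 10.9 ± 8.68 CPM, a log2 fold change of -10.95 ± 1.00 (SE; edgeR adjusted p 4.7e-11), and miR-36-3p from 41237 ± 15635 to 301 ± 115 CPM, a log2 fold change of -7.09 ± 0.62. miR-35-5p, with no read at 500 min, was at least 456-fold lower and miR-39-3p at least 17.99-fold lower. miR-40-3p, with 1 read at 500 min, had a 60 min to 500 min ratio of 544 (95% counting interval 96.9 to 21570), and miR-38-5p, with 2 reads, a ratio of 79.9 (21.4 to 671). miR-35-3p had a log2 fold change of -8.77 and miR-42-3p of -5.76. Outside the family, miR-74-5p fell from 77818 ± 20141 to 1083 ± 184 CPM (log2 fold change -6.17 ± 0.48, edgeR adjusted p 3.73e-12), and miR-253-3p, miR-249-3p and miR-64-3p had log2 fold changes of -6.06, -6.05 and -5.26. Of the 80 miRNAs, 64 had 3 libraries at 1 stage all above those at the other; among all 128, 70 did (54.7%, where chance gives 10%). Of the 24 named, miR-39-3p alone lost its call when 1 library was left out (adjusted p 0.0537 without 500 min replicate 1) and miR-790-5p alone without the low-count filter (0.0534). miR-249-3p had a log2 fold change of -9.86 without 500 min replicate 1.

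The sign of small fold changes depends on scaling. The median log2 fold change of all 128 miRNAs between 60 and 500 min was 0.30 with TMM, 0.58 with DESeq2 size factors and 0.08 with total counts, and medians of lists are given here relative to that of all miRNAs. No list median changed sign relative to it under these scalings, and without any 1 library that of the heterochronic miRNAs alone did (-0.88 without 500 min replicate 2). Without 60 min replicate 1 the median was 2.15, but leaving out a library and computing everything anew also changed the arms kept, from 128 to between 134 and 139, and the library that TMM takes as its reference, in 23 of 24 cases. Libraries named here as decisive are therefore those whose removal mattered with the filter and the TMM factors kept (median then 0.06 to 0.94), a setting chosen after the data were seen.

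The mir-35 family, made by the mother and the early embryo and needed for embryonic viability, lies on chromosome II of WBcel235 with mir-35 at 11537608 to 11537704 and mir-41 at 11538308 to 11538404, both outside protein-coding genes. Of its 14 tested arms, 12 fell and 2 did not pass the test (13 fell adjusted over the list alone; fry adjusted p 1e-08). The list's median was -7.00 on the log2 scale relative to all miRNAs (-6.03 in absolute terms with all-zero arms at their bounds). Its share of counts was 5.02% ± 0.314 at 60 min, 6.65% ± 1.81 at 120 min, 0.997% ± 0.315 at 270 min and 0.0473% ± 0.0195 at 500 min (SD, n = 3 each). The arms not called were miR-38-3p, with 4 reads at 60 min and 0 at 500 min, and miR-42-5p, with a log2 fold change of -0.16 ± 0.67. Calls were lost without 1 library for miR-36-5p (adjusted p 0.182 without 60 min replicate 3 and 0.0572 without 500 min replicate 1), miR-37-3p (60 min replicate 3, 500 min replicate 1 or 2, up to 0.0963) and miR-41-5p (60 min replicate 1, 500 min replicate 1 or 3, up to 1), and miR-38-3p gained one without 60 min replicate 3 (0.0458). In 60 min replicate 3, miR-36-5p had 112 reads, against 5 and 0 in the others.

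**Figure D2:**
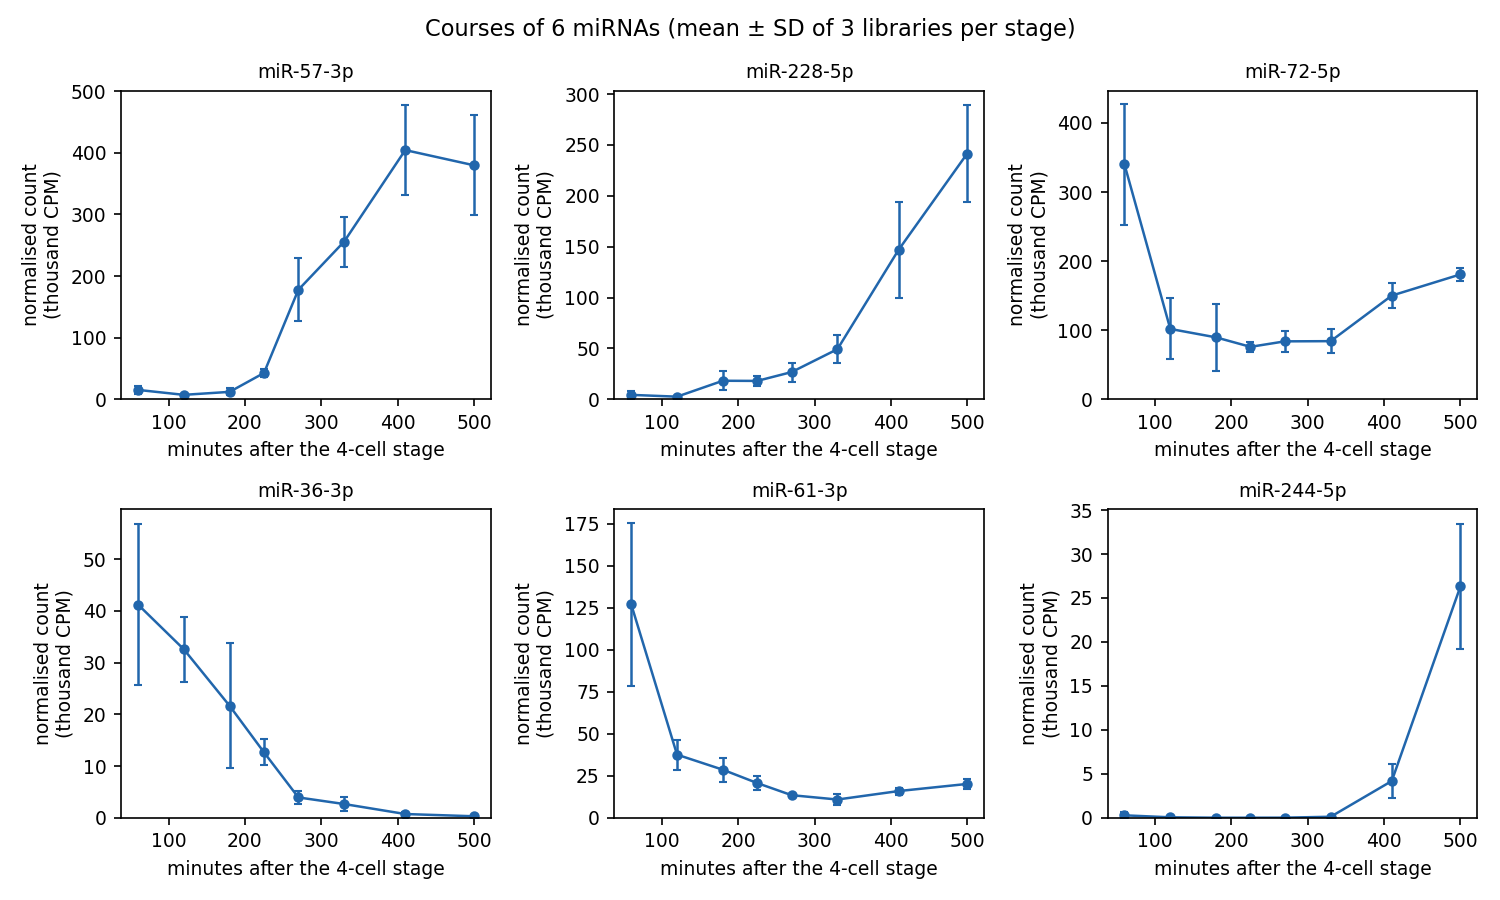
TMM-scaled level (CPM divided by 1000, y axis) of 6 miRNAs against time after the 4-cell stage (minutes, x axis), with points and bars for the mean and SD of 3 libraries. miR-36-3p goes from 41237 CPM at 60 min to 301 CPM at 500 min, and miR-57-3p from 42742 CPM at 225 min to 177594 CPM at 270 min.

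The mir-64 to mir-66 and mir-229 cluster, which lies in introns of gcn-1 on chromosome III (mir-229 at 2172452 to 2172566, mir-64 at 2172848 to 2172957), supplied 42.6% ± 8.45 of counts at 60 min and 54.3% ± 5.17 at 120 min. At 500 min it supplied 5.97% ± 1.21. Of its 8 tested arms, 7 fell and 1 did not pass the test (7 adjusted over the list alone; fry adjusted p 1.03e-06; median -2.94 relative to all miRNAs). miR-229-3p had a log2 fold change of -3.61 ± 0.44 and miR-64-5p of -2.76 ± 0.37. The call of miR-229-5p was lost without 500 min replicate 1 (adjusted p 0.0629) and with DESeq2 (0.0549). That of miR-66-5p (log2 fold change -1.09 ± 0.45) was lost without 60 min replicate 1 or any 500 min replicate (up to 0.0966) as well as with DESeq2 size factors, DESeq2, no filter, without the 5 most abundant miRNAs and in the fit of 6 libraries (up to 0.0963).

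The mir-58 family, related to bantam of insects, rose: 4 of 7 tested arms were higher at 500 min, 1 was lower and 2 did not pass the test (5 adjusted over the list alone; fry adjusted p 2.88e-06; median 1.79 relative to all miRNAs, and 0.93 without 60 min replicate 1). miR-81-3p (mir-81, X, 2431072 to 2431179) had a log2 fold change of 4.20 ± 0.68, miR-58a-3p (mir-58a, in an intron of Y67D8A.2 on IV, 3233254 to 3233350) of 4.19 ± 0.60, miR-82-3p (mir-82, in an intron of gid-2 on X, 2435258 to 2435354) of 3.63 ± 0.51 and miR-58a-5p of 2.09 ± 0.59. The lower arm was miR-82-5p, with 65 reads at 60 min and 15 at 500 min, whose call was lost without any of 19 libraries (edgeR adjusted p up to 0.665, without 60 min replicate 3), with either other scaling, DESeq2, no filter, without the 5 most abundant miRNAs and in the fit of 6 libraries (up to 0.304). The share of the family rose between 120 and 180 min, from 1.61% ± 0.294 to 12.5% ± 3.18, and was 20.8% ± 4.60 at 500 min. In 60 min replicate 3, miR-81-3p had 2501 reads, against 97 and 75 in the other 60 min libraries, and without it the log2 fold change of miR-81-3p was 6.52.

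Of the mir-51 family, which includes the worm's miR-99 and miR-100 relatives, 3 of 8 tested arms rose and 5 did not pass the test (3 adjusted over the list alone; fry adjusted p 0.000602; median 3.15 relative to all miRNAs, 2.00 without 500 min replicate 1, and 2.26 in absolute terms with all-zero arms at their bounds). They were miR-54-3p, miR-53-3p, with a ratio of 62.1 (95% counting interval 17.0 to 516) and 2 reads at 60 min (fitted log2 fold change 5.76, and 9.72 without 60 min replicate 3), and miR-52-5p, with a log2 fold change of 2.01 ± 0.48. The family made up 0.229% ± 0.0281 of counts at 60 min, 0.932% ± 0.308 at 180 min and 0.525% ± 0.201 at 500 min. The call of the list was lost without the low-count filter (fry adjusted p 0.113), and miR-51-5p and miR-55-3p were called higher without 60 min replicate 1 (edgeR adjusted p 0.0101 and 0.0212).

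Of 5 tested arms of tissue-restricted miRNAs, 4 rose and 1 fell (5 adjusted over the list alone; fry adjusted p 1.03e-06; median 7.60 relative to all miRNAs, and 3.49 in absolute terms with all-zero arms at their bounds). Muscle miR-1-5p (mir-1, I, 6172662 to 6172757) had a log2 fold change of 5.73 ± 0.89 and miR-1-3p was at least 11.3-fold higher. Neuronal miR-124-5p, from an intron of trpa-1 on IV (11871738 to 11871833), and lsy-6-3p (lsy-6, V, 10647232 to 10647304) rose as given above. Intestinal miR-60-3p was the member that fell, with a log2 fold change of -1.76 ± 0.72, and its call was lost without 60 min replicate 1 or 3 or 500 min replicate 1 or 2 (edgeR adjusted p up to 0.242), with DESeq2 size factors (log2 fold change -1.07), DESeq2, no filter, without the 5 most abundant miRNAs and in the fit of 6 libraries (up to 0.182). The share of the list was highest in the middle of the timecourse, at 0.0362% ± 0.0219 at 60 min, 0.192% ± 0.0354 at 270 min and 0.0802% ± 0.00540 at 500 min.

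The mir-2, mir-44 and mir-72 lists had tested arms on both sides. Both arms of a hairpin counted, so opposite directions need not mean that related sequences diverged. Of mir-44 itself only the 5p arm could be judged, as miR-44-3p had 0 reads. In the mir-2 family, miR-2-3p rose (log2 fold change 2.75 ± 0.65), as did miR-2-5p (ratio 60.9, 95% counting interval 10.7 to 2424, 1 read at 60 min; fitted log2 fold change 5.22, and 8.59 without 60 min replicate 1), while miR-43-3p (-4.76 ± 0.49) and miR-250-3p (-3.23 ± 0.55) fell and 2 of the 6 tested arms did not pass the test. In the mir-44 family of 4 tested arms, miR-44-5p rose (1.29 ± 0.35), miR-61-3p fell (-2.65 ± 0.38) and 2 did not pass the test. In the mir-72 family of 6 tested arms, miR-72-3p (1.93 ± 0.53) and miR-74-3p (2.80 ± 1.18) rose, miR-74-5p fell, miR-72-5p was called lower (-0.91 ± 0.37) and 2 did not pass the test. Adjusted over the list alone, 4, 2 and 4 arms were called. All 3 lists tested lower on balance, with fry adjusted p of 0.000861, 0.0351 and 0.00191 and medians of -1.74, -1.43 and -0.90 relative to all miRNAs. Without 60 min replicate 1 these medians were -0.75, -2.31 and -0.12. The calls of the mir-2 and mir-72 lists held without any 1 of the 6 libraries with the TMM factors kept (fry adjusted p up to 0.00947 and 0.0175), but not with the factors computed anew (up to 0.908 without 60 min replicate 1 and 0.630 without 500 min replicate 1). That of the mir-44 list was lost without 60 min replicate 3 or 500 min replicate 1, 2 or 3 (0.150, 0.0802, 0.0937 and 0.0611), with DESeq2 size factors (0.145) and without the 5 most abundant miRNAs (0.0701). miR-72-5p lost its call without 60 min replicate 1 or 3 or any 500 min replicate (edgeR adjusted p up to 0.0892), with DESeq2 size factors (log2 fold change -0.52), DESeq2 and in the fit of 6 libraries (up to 0.110). Its log2 fold change was 0.28 without 60 min replicate 1 with the TMM factors computed anew. miR-74-3p lost it without 60 or 500 min replicate 2 or 3 (up to 0.150), with no filter and in the fit of 6 libraries (up to 0.251), and had a log2 fold change of 8.23 without 60 min replicate 1. miR-44-5p and miR-72-3p lost theirs with no filter (0.133 and 0.117). As shares of counts, which need no scaling, the families went from 1.03% ± 0.172 to 0.254% ± 0.0469, from 10.2% ± 1.32 to 4.42% ± 0.534 and from 31.6% ± 1.28 to 13.8% ± 0.994. Shares also fall where other miRNAs take up more of the counts, as miR-57-3p did (1.06% to 25.4%). A fall in share therefore does not show that the amount of a family fell.

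**Figure D3:**
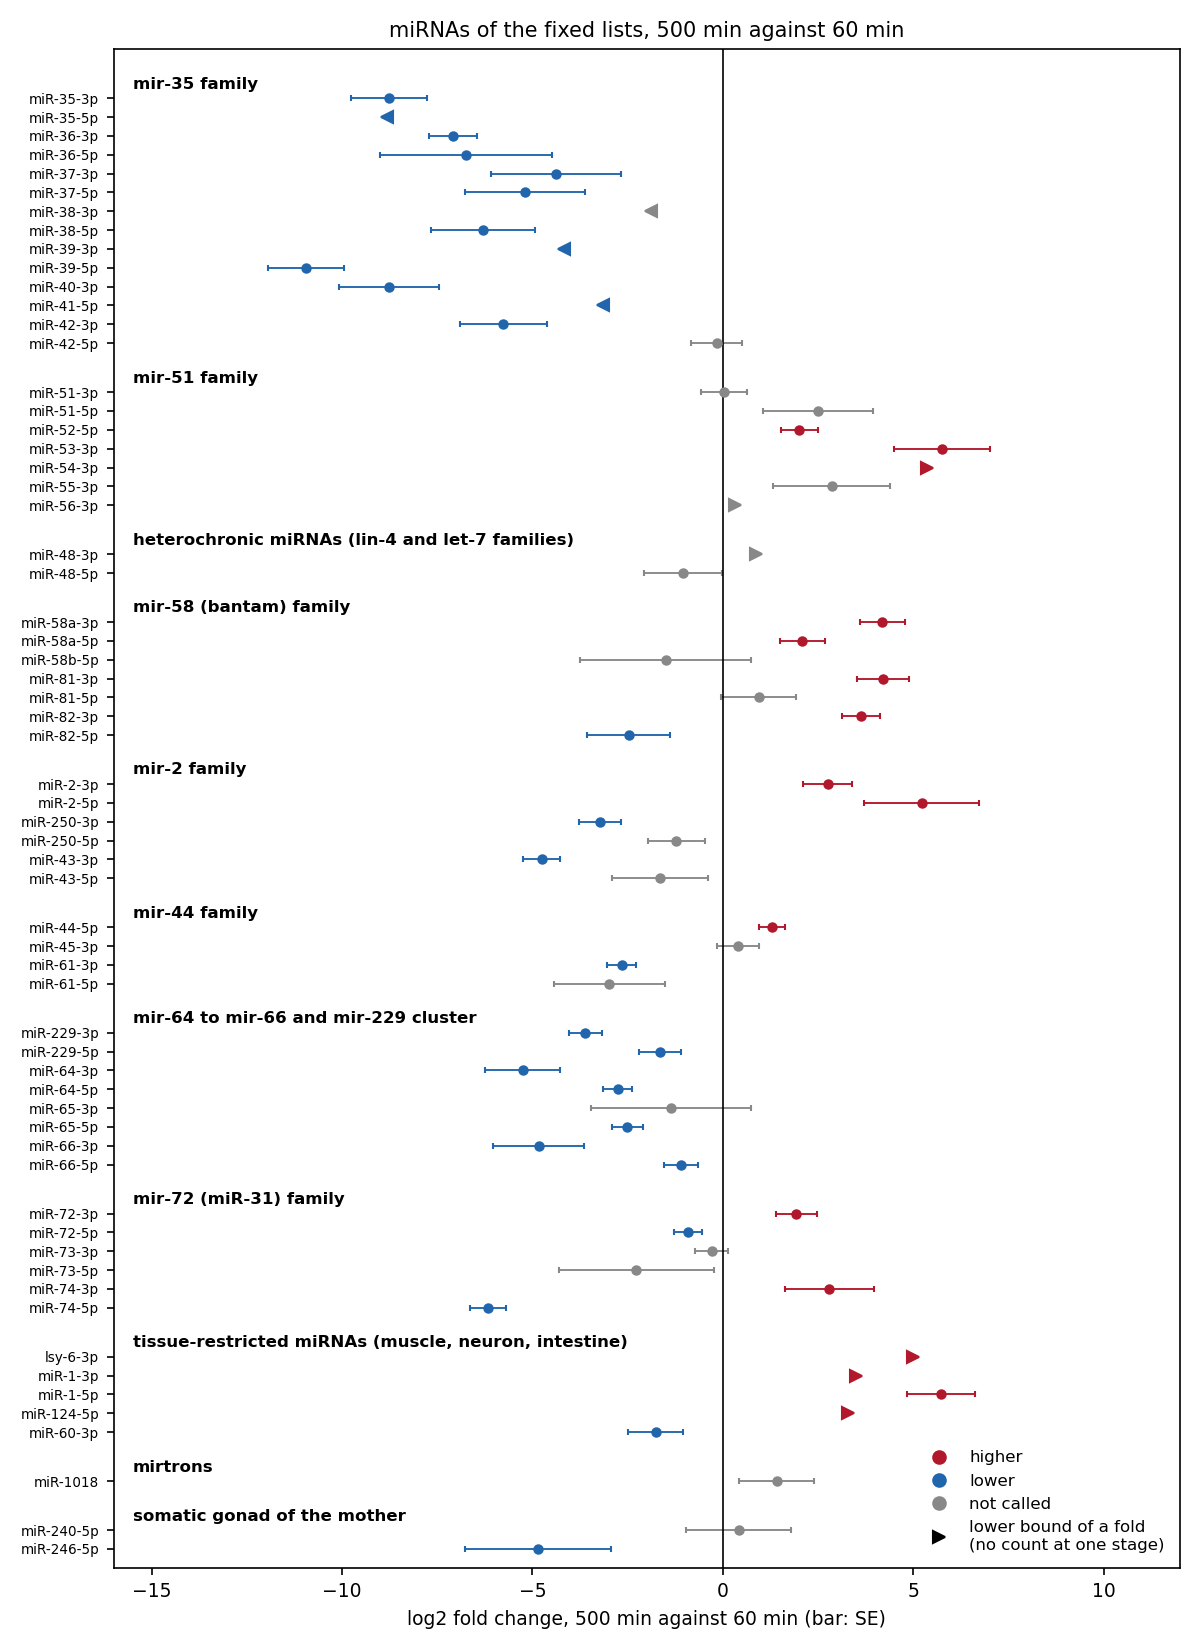
Log2 fold change at 500 min against 60 min (x axis) of each tested arm of the fixed lists other than that of miRNAs conserved among bilaterians. Bars give the SE of fitted values and triangles the lower bounds against the floor. Arms whose bound lies under 1-fold are not drawn. All called arms of the mir-35 family lie left of 0 and 4 of the 5 called arms of the mir-58 family right of 0.

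The miRNAs conserved among bilaterians were a broad list. It takes in the mir-51, mir-2 and mir-72 families, most of the mir-58 family and the heterochronic miRNAs. The list names hairpins and not the conserved arm, so either arm of a hairpin is included in its 49 tested arms. Of these, 28 rose, 6 fell and 15 did not pass the test (34 called adjusted over the list alone; fry adjusted p 3.35e-06; median 2.50 relative to all miRNAs). Beyond the families above, miR-87-3p had a log2 fold change of 4.56 ± 0.80, miR-34-3p, with 4 reads at 60 min, of 4.96 ± 1.54 (10.39 without 60 min replicate 1) and miR-50-5p of 1.98 ± 0.53. The list made up 40.7% ± 6.59 of counts at 60 min, 28.6% ± 2.13 at 120 min and 82.04% ± 3.26 at 500 min. Its member miR-235-3p, with 43962 reads at 60 min and 38502 at 500 min, was not called (-0.69 ± 0.68) but was called higher without 60 min replicate 3 (log2 fold change 1.47, edgeR adjusted p 0.0147). Calls were lost without 1 library for miR-71-5p (-1.67 ± 0.71; 60 min replicate 3, 500 min replicate 2 or 3, up to 0.473), miR-236-3p (60 min replicate 2 or 3, 500 min replicate 2, up to 0.0966) and miR-50-3p (60 min replicate 2, 500 min replicate 3, up to 0.0910). The same held for miR-83-5p (any 60 min replicate, 500 min replicate 1 or 3, 410 min replicate 3, up to 0.103), miR-87-5p (60 min replicate 2 or 3, 500 min replicate 2, 410 min replicate 3, up to 0.153) and miR-49-5p (60 min replicate 1, 0.0521). With no filter miR-71-5p, miR-236-3p, miR-50-3p, miR-83-5p and miR-87-5p were not called (up to 0.451), nor was miR-87-5p in the fit of 6 libraries (0.177). miR-71-5p was not called with DESeq2 size factors, DESeq2, without the 5 most abundant miRNAs or in the fit of 6 libraries (up to 0.123), and its log2 fold change was -0.59 without 60 min replicate 3. miR-71-3p was called higher without 60 min replicate 3 (0.0125) and with DESeq2 size factors (0.0207), and miR-67-3p without 60 min replicate 2 (0.0433).

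Few reads came from the 3 remaining lists. Of the heterochronic miRNAs, which time larval development, 2 arms were tested and 0 were called by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 with DESeq2): miR-48-5p had 194 reads at 60 min, 189 of them in replicate 3, and 118 at 500 min, and miR-48-3p had 0 and 6. The fitted median of these arms was 2.13 on the log2 scale and -0.08 with miR-48-3p at its bound. Of the list of mirtrons only miR-1018 was tested, whose hairpin lies outside protein-coding genes in the annotation used, and edgeR did not call it (log2 fold change 1.42 ± 0.99; 0 adjusted over the list alone, 0 at an unadjusted p under 0.05), while DESeq2 did (1 call, log2 fold change 1.99, adjusted p 0.0433). Of the mother's somatic gonad miRNAs, miR-246-5p was called lower (-4.87 ± 1.92, edgeR adjusted p 0.0320; 1 adjusted over the list alone) and miR-240-5p was not (0.41 ± 1.37). Of the 72 reads of miR-246-5p at 60 min, 68 were in replicate 3, and its call was lost without 60 min replicate 3 (log2 fold change -2.36, edgeR adjusted p 0.366), 500 min replicate 2 or 3 (0.0954 and 0.0897) and with DESeq2 size factors (0.0574), DESeq2 (0.112), no filter (0.158) and without the 5 most abundant miRNAs (0.0502). Without 500 min replicate 1 its log2 fold change was -8.65.

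Over the 24 libraries, the mir-35 share fell with time (Pearson r -0.841, Spearman rho -0.964; each permutation p 1e-05, the smallest the resamples can give; adjusted p 3e-05 over the 3 shares correlated). Within replicate numbers 1, 2 and 3, r was -0.900, -0.836 and -0.872 (permutation p 0.0022, 0.00727 and 0.00435; n = 8 each), and without 2 of the 500 min libraries, the times farthest from the median, it was -0.845. The mir-51 share had r 0.208 and rho 0.223 (permutation p 0.330 and 0.298; adjusted 0.366 and 0.447), with r of 0.386, 0.0913 and 0.108 within replicate numbers and 0.291 to 0.442 without 2 of the 500 min libraries. With miR-57-3p left out of the total, it rose with time (r 0.489, permutation p 0.0158, adjusted p 0.0237). The heterochronic share had r -0.198 and rho -0.0236 (permutation p 0.366 and 0.917; adjusted 0.366 and 0.917). Its r was 0.419, 0.413 and -0.769 within replicate numbers 1, 2 and 3, -0.213 to -0.0662 without 2 of the 500 min libraries, and 0.0512 without 60 min replicate 3.

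Changes between neighbouring stages were fewer than between the ends. Across the 7 steps, 38 miRNAs were called at least once, and 37 of these also differed among the 8 stages; 50 others differed among the stages without passing the test at any single step. The steps with the most calls were from 330 to 410 min with 14 and from 120 to 180 min with 12.

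**Figure D4:**
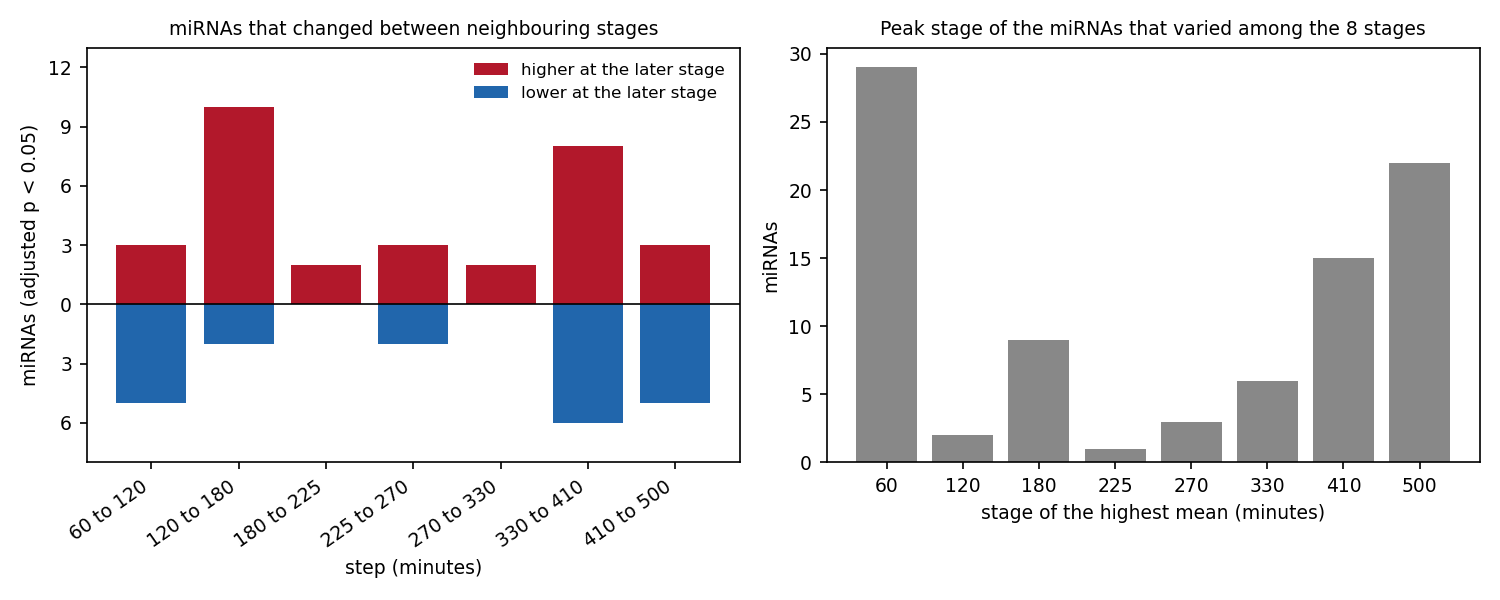
Left, number of miRNAs called higher or lower (y axis) at each step between neighbouring stages (x axis); right, number of the 87 varying miRNAs (y axis) whose mean TMM-scaled level is highest at each time (minutes, x axis). The step from 330 to 410 min has 8 higher and 6 lower, and 29 miRNAs peak at 60 min against 22 at 500 min.

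From 60 to 120 min, 3 miRNAs rose and 5 fell (35 at an unadjusted p under 0.05). miR-54-3p was at least 14.6-fold higher, miR-228-3p had a ratio of 45.1 (95% counting interval 7.94 to 1794; fitted log2 fold change 5.46, and 8.61 without 60 min replicate 3) and miR-1-5p a log2 fold change of 3.66 ± 0.87. miR-253-3p, miR-87-5p and miR-61-3p fell, with log2 fold changes of -2.36, -1.85 and -1.76 (edgeR adjusted p 0.0197, 0.0197 and 0.00212). Calls were lost for miR-253-3p without any 120 min replicate (adjusted p up to 0.127) and for miR-87-5p without 60 min replicate 1 or 120 min replicate 2 or 3 (up to 0.107), and for both with either other scaling, no filter, without the 5 most abundant miRNAs and in the fit of 6 libraries (up to 0.370). In that fit miR-61-3p, miR-1-5p and miR-228-3p were not called either (0.218, 0.183 and 0.0539), nor was miR-61-3p with no filter (0.269). The log2 fold change of miR-61-3p was -1.05 with DESeq2 size factors and -0.85 with total counts. The count of 8 was 17 without 60 min replicate 2, 13 without 60 min replicate 3, 14 with DESeq2 size factors (11 higher, 3 lower), 16 with total counts (14 and 2) and 25 with DESeq2 (20 and 5), but 3 with no filter and 2 in the fit of 6 libraries.

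From 120 to 180 min, 10 miRNAs rose and 2 fell (25 at an unadjusted p under 0.05). miR-81-3p rose from 1346 ± 477 to 23197 ± 5355 CPM, a log2 fold change of 4.11 ± 0.68 (edgeR adjusted p 8.37e-05), and its other arm, miR-81-5p, had a log2 fold change of 3.72 ± 1.00. miR-8199-3p was at least 34.4-fold higher. miR-789-3p, at 40.6 ± 9.54 CPM at 120 min, was at least 17.1-fold lower and miR-39-5p had a log2 fold change of -2.43 ± 0.66. Calls were lost without 1 library for miR-39-5p (180 min replicate 1 or 2 or 120 min replicate 2, adjusted p up to 0.0918), miR-8199-3p (any 120 min replicate, 180 min replicate 1 or 2, up to 0.110) and miR-81-5p (120 min replicate 3, 0.0628). With no filter they were lost for miR-8199-3p and miR-81-5p (0.0733 and 0.0806). The count of 12 was 7 without 120 min replicate 3, 19 with DESeq2 size factors (10 higher, 9 lower) and 21 with DESeq2 (11 and 10). Total counts gave 10 higher and 4 lower.

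The next 3 steps had few calls. From 180 to 225 min, 2 miRNAs rose (13 at an unadjusted p under 0.05): miR-57-3p, with a log2 fold change of 1.82 ± 0.38 (edgeR adjusted p 0.00382), and miR-236-3p, with 1 read at 180 min and a ratio of 104 (95% counting interval 18.1 to 4151). From 225 to 270 min, 3 rose and 2 fell (11 at an unadjusted p under 0.05). miR-57-3p rose again, from 42742 ± 6862 to 177594 ± 51236 CPM (2.05 ± 0.38, adjusted p 0.000682), with miR-87-5p (1.97 ± 0.53) and miR-1822-5p, at least 19.0-fold higher, while miR-36-3p (-1.68 ± 0.48) and miR-229-3p (-1.38 ± 0.40) fell. From 270 to 330 min, lsy-6-3p (4.81 ± 1.22) and miR-87-5p (1.93 ± 0.52) rose (8 at an unadjusted p under 0.05). Of the 9 calls, those of miR-57-3p at both steps held without any 1 library. The count from 180 to 225 min was 1 without 225 min replicate 1, 180 min replicate 2 or 180 min replicate 3, with miR-236-3p lost (adjusted p up to 0.230). The count from 225 to 270 min was 1 without any 225 min replicate, 270 min replicate 1, 410 min replicate 3 or 500 min replicate 2, 2 without 270 min replicate 2 or 3, and 3 without 60 min replicate 1 or 120 min replicate 2. The count from 270 to 330 min was 0 without any of 16 libraries, 1 without 60 min replicate 1 or 2, and 5 without 60 min replicate 3 or 270 min replicate 1, where lsy-6-3p had a log2 fold change of 8.37 without the latter. With no filter, without the 5 most abundant miRNAs (miR-57-3p among them) and in the fits of 6 libraries, the counts at the 3 steps were 2, 1 and 9, then 3, 1 and 6, then 0, 0 and 0, and DESeq2 gave 5 at the last. The calls of miR-36-3p and miR-229-3p (no filter, without the 5), miR-1822-5p (without the 5), miR-87-5p from 225 to 270 min (no filter) and lsy-6-3p and miR-87-5p from 270 to 330 min (all 3) were lost there.

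From 330 to 410 min, 8 miRNAs rose and 6 fell (25 at an unadjusted p under 0.05). miR-242 (IV, 4274247 to 4274342) rose from 13.7 ± 8.81 to 892 ± 69.9 CPM, a log2 fold change of 6.09 ± 1.36 (edgeR adjusted p 0.00353), miR-244-5p from 123 ± 107 to 4186 ± 1905 CPM (5.06 ± 1.25), and miR-1022-3p was at least 14.1-fold higher. The largest falls were in the mir-35 family: miR-38-5p with a ratio of 35.2 (95% counting interval 9.09 to 301), miR-35-5p (-4.77 ± 1.32) and miR-39-5p (-3.38 ± 0.69). Calls were lost without 1 library for miR-35-5p and miR-38-5p (410 min replicate 1 or 3 or 330 min replicate 2, adjusted p up to 0.102 and 0.161), miR-244-5p (330 min replicate 1 or 2, up to 0.0781) and miR-1022-3p (any 330 or 410 min replicate, 500 min replicate 1 or 2, up to 0.123). Other settings ended the calls of miR-1022-3p (total counts, no filter, without the 5 most abundant miRNAs, up to 0.0645) and miR-35-5p (fit of 6 libraries, 0.0536). The count of 14 was 8 without 330 min replicate 1, 7 without 330 min replicate 2 and 9 without 410 min replicate 1 or 3. Total counts gave 4 higher and 12 lower.

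From 410 to 500 min, 3 miRNAs rose and 5 fell (14 at an unadjusted p under 0.05). miR-788-3p (X, 8485294 to 8485371) went from no read to 505 ± 402 CPM, at least 311-fold higher (edgeR adjusted p 0.000887), and miR-245-3p from 3499 ± 1459 to 62735 ± 31176 CPM (4.16 ± 0.73). miR-789-3p, which had fallen between 120 and 180 min, rose from 273 ± 133 to 4847 ± 1186 CPM (4.15 ± 0.93). miR-41-5p was at least 20.4-fold lower, miR-8199-5p at least 4.40-fold lower and miR-39-5p fell further (-3.83 ± 0.83). Calls were lost without 1 library for miR-41-5p (any of 13, adjusted p up to 0.197, without 500 min replicate 1) and miR-8199-5p (any of 15, up to 0.240, without the same). They were also lost for both with DESeq2 size factors (0.0569 and 0.0582) and for miR-8199-5p with no filter (0.170). The count of 8 was 4 without 500 min replicate 2 and 5 without 120, 180 or 330 min replicate 1, 120, 180 or 225 min replicate 2, or 180, 225, 410 or 500 min replicate 3, and 5 with DESeq2 size factors (3 higher, 2 lower) or without the low-count filter. With total counts there were 3 higher and 8 lower.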

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

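Calls depended on scaling and on single libraries. Of 121 values for a named miRNA in a comparison, 98 were calls, and 47 of these kept direction and call under every setting. Under every setting that left out no library 65 did so. The number was 63 without any 1 library with the filter and TMM factors kept (chosen after the data were seen), and 60 without any 1 library with both computed anew. Of the 98, the number kept was 94 with total counts, 91 with DESeq2, 88 with DESeq2 size factors and 73 with no low-count filter, where all arms with a count share the adjustment. Without the 5 most abundant miRNAs 77 were kept and 13 lost, and in fits of the 6 libraries of both stages 69 and 15. A called direction turned for miR-72-5p and miR-66-5p, both without 60 min replicate 1 with TMM computed anew, and for 0 with the factors kept. The number of miRNAs that differed among the stages (61 to 94 without 1 library or number), those for 500 min against 60 min (59 to 81) and the peaks at 410 or 500 min (27 to 46) stayed within 1.5 times of the values in the report. The mir-35, mir-58, mir-64, tissue-restricted and conserved lists kept direction and call (fry adjusted p up to 0.0120 without 1 library or number), and r of the mir-35 share lay between -0.900 and -0.829 under every setting. At the depths of 60 and 500 min the self-test found 27.1% of 4-fold changes and at those of 270 and 330 min 30.5%, so an arm without a call is not shown to be unchanged. Depth was not separated there from the spread between libraries. It sets the floors, where 3 counts over the TMM-scaled libraries are 7.575 CPM at 60 min and 3.84 CPM at 500 min.

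Leaving out a library and computing everything anew also changed the scaling. The fits kept 134 to 139 arms in place of 128, and 23 of 24 took another library as the TMM reference. The mean log2 TMM factor at 500 min minus that at 60 min was -0.11 with all libraries, -1.24 to -0.05 in these fits, -0.29 to 0.11 with the factors kept, and -1.48 to 0.39 when each library in turn served as the reference for all 24. With each as the reference, the median log2 fold change of all miRNAs between 60 and 500 min ran from -0.21 to 1.59, so absolute signs of small changes are set by this choice. Among the fits without 1 library, some calls were lost only when both were computed anew. They were those of miR-37-5p between 60 and 500 min (adjusted p 0.0677), miR-39-5p from 410 to 500 min (0.0576), miR-61-3p from 60 to 120 min (15 libraries, up to 0.287) and miR-789-3p from 120 to 180 min (0.0547). The call of miR-61-3p was also lost with no filter and in the fit of 6 libraries.

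The count from 60 to 120 min (8 in the report) was 14 with DESeq2 size factors, 16 with total counts, 3 with no filter, 25 with DESeq2 and 2 in the fit of 6 libraries. From 120 to 180 min (12) it was 19 with size factors and 21 with DESeq2. From 180 to 225 min (2) it was 1 without the 5 most abundant miRNAs and 9 with 6 libraries. From 225 to 270 min (5) it was 3 with no filter and 1 without the 5, and from 270 to 330 min (2) 0 with no filter, without the 5 and with 6 libraries, and 5 with DESeq2. From 410 to 500 min (8) it was 5 with size factors and 5 with no filter. Peaks at 60 min (29) were 16 with total counts, and the middle-stage counts of 2 higher and 9 lower were 10 and 5. The mir-51 list had fry adjusted p 0.113 with no filter, the mir-44 list 0.145 with size factors and 0.0701 without the 5, and the gonad list had 0 calls with size factors, with no filter and without the 5. The mir-51 share had r 0.489 without miR-57-3p in the denominator, and the heterochronic share r 0.419, 0.413 and -0.769 within replicate numbers 1, 2 and 3 and 0.0512 without 60 min replicate 3. Apart from the number of arms tested with no filter and the number of libraries in the small fits, the cause was not tested.

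Between 60 and 500 min, signs of values that were not called turned for miR-42-5p (0.33 with size factors, 0.31 with DESeq2, 0.13 without the 5, 0.10 with 6 libraries), miR-73-3p (0.27 and 0.27 with size factors and DESeq2) and miR-235-3p (0.0762, 0.0774 and 0.0628 with size factors, DESeq2 and 6 libraries). With no filter they turned for miR-51-3p (-0.14), miR-45-3p (-0.0390) and miR-240-5p (-0.46). The cause was not tested. Without 1 library or replicate number, log2 fold changes that changed sign ran from -1.13 to 0.28 for miR-72-5p, -1.42 to 0.13 for miR-66-5p, -0.60 to 0.84 for miR-42-5p, -0.60 to 1.26 for miR-51-3p, -2.26 to 2.66 for miR-48-5p, -6.69 to 4.73 for miR-58b-5p, -1.74 to 0.0816 for miR-250-5p, -3.19 to 2.53 for miR-43-5p, -0.0149 to 1.73 for miR-45-3p. They ran from -7.54 to 2.21 for miR-65-3p, -0.72 to 0.99 for miR-73-3p, -7.36 to 4.77 for miR-73-5p, -1.39 to 1.47 for miR-235-3p and -0.47 to 2.16 for miR-240-5p.

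Over the same settings, the counts of calls at the 7 steps in order of time ran from 6 to 21, 6 to 16, 1 to 3, 1 to 6, 0 to 5, 6 to 17 and 2 to 10. Peaks at 60 min ran from 11 to 31, middle-stage miRNAs from 0 to 4 higher and 4 to 10 lower, and calls of the gonad list from 0 to 1. Fry adjusted p ran from 0.000105 to 0.908 for the mir-2 list, 0.00489 to 0.843 for the mir-44 list and 0.000113 to 0.630 for the mir-72 list, and r of the heterochronic share from -0.402 to 0.402.

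The labels do not pair the samples by replicate number. Deviations of same-numbered libraries from their stage means had a mean correlation of 0.109 (lowest -0.136, over 0.1 in 40 of 84 pairs). For libraries of different numbers it was -0.0544. Deviations from a stage mean cancel out within the stage, so the second value follows largely from the first and adds no evidence. Of the 24 libraries, 21 correlated best with their own number, a hint from the data, not the design. A batch shared by the libraries of a number is therefore possible, and the main tests do not allow for it. With the number as a block, 13 miRNAs were called from 60 to 120 min, 4 from 180 to 225 min and 0 in the gonad list. Of the 98 calls of named miRNAs 95 were kept. Between 60 and 500 min miR-36-5p, miR-83-5p and miR-246-5p were not called under the block (adjusted p 0.0566, 0.0503 and 0.0539), and miR-71-3p was (0.00532).

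Other assignments of the libraries to stages gave fewer calls than the real one in every case. For the number that differed among the stages, 1 of 100 assignments, the real one, reached 87, and the next gave 7. Of all 10 splits of the 6 libraries of a pair, too few for a share under 0.05, 1 reached the real count in each comparison, the real one. The counts were 80 against 1 in the next for 500 min against 60 min, and at the 7 steps in order of time 8 against 7, 12 against 4, 2 against 0, 5 against 0, 2 against 1, 14 against 0 and 8 against 1.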

Other observations

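The tests of the middle stages, of 60 min replicate 3 and of position along chromosomes were chosen after the result was seen. Those of neighbouring hairpins and of arms were written before. Some miRNAs departed from both ends of the timecourse in its middle. Against the mean of 180 to 330 min, 2 miRNAs were lower at both 60 and 500 min (edgeR, adjusted p under 0.05 against each end). miR-45-3p went from 242 ± 142 CPM at 60 min to 1426 ± 85.8 at 270 min and 320 ± 45.1 at 500 min, with log2 fold changes of the middle of 2.06 ± 0.50 against 60 min and 1.67 ± 0.49 against 500 min. miR-8199-5p rose from 25.6 ± 28.5 CPM at 60 min to 405 ± 226 at 180 min and had no read at 500 min. With total counts 10 were higher in the middle, these 2 among them, and miR-8199-5p lost its call without 60 min replicate 2 or 3, 180 min replicate 1 or 270 min replicate 2. Without all libraries of replicate number 2, 0 were higher, so miR-45-3p lost its call there too.

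Another 9 were lower in the middle than at both ends, by the mean of the fitted log2 levels over 180 to 330 min. They were miR-72-5p, miR-75-5p, miR-789-3p, miR-1022-3p, miR-235-3p, miR-244-5p, miR-245-3p, miR-87-5p and miR-1820-5p. miR-87-5p was not low throughout. It stood at 246 ± 94 CPM at 180 min but at 4172 ± 673 at 330 min. The latter lay above its 1464 ± 317 at 60 min and 3378 ± 997 at 500 min. miR-72-5p, the most abundant species at 60 min, stood at 340100 ± 87580 CPM there, 75970 ± 7199 at 225 min and 180900 ± 9681 at 500 min (middle against the ends -2.03 ± 0.26 and -1.12 ± 0.27). miR-75-5p went from 309 ± 326 CPM to 0 at 180 min and 77.8 ± 46.8 at 500 min. Without 60 min replicate 3 the 9 were 4, miR-72-5p, miR-75-5p, miR-789-3p and miR-1022-3p, and with total counts 5, these and miR-244-5p. miR-1022-3p, at 26.2 ± 45.5 CPM at 60 min, lost its call without 60 min replicate 1. Of 100 assignments of the libraries to stages, 1, the real one, gave 9 lower (next 3), and 1, the real one, gave 2 higher (next 0). Such assignments mix all stages, so they show that levels depend on stage. They cannot show that the middle in particular departs from both ends.

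60 min replicate 3 stood apart from the other 60 min libraries: in it 13 miRNAs were raised at least 8-fold, among them miR-70-3p (955 reads against 2 and 0), miR-49-5p (194 against 2 and 3), miR-81-3p (2501 against 97 and 75) and miR-245-3p (761 against 24 and 29), and 4 were lowered (miR-359, miR-5546-3p, miR-67-3p and miR-87-3p). Embryos of a later sampled stage in the tube were argued against as the source of most of the raised miRNAs. The largest admixture was set by the abundant miRNAs of each later stage. It explained a median of 4.53% of the excess over the raised miRNAs for 120 min embryos, the highest of the later stages (upper quartile 6.35%). The raised miRNAs named above were highest at 500 min. For 500 min embryos the admixture was at most 2.24% (median explained 0.05%, upper quartile 4.14%). A median does not cover single miRNAs, some of which may owe more to an admixture. For depth, the counts of this library were thinned to the depth of the shallowest 60 min library. Its score on the third principal component was then 17.94 (16.87 to 18.72 over 100 draws), against 18.03 before and at most 9.08 in the others. The component was fitted with this library at full depth, so the score could hardly fall and does not decide about depth. Tissue of the mother could explain the difference and stayed open. Of the list miRNAs with 10 or more reads in a 60 min library, 100% (3 of 3: miR-48-5p with 189, miR-246-5p with 68 and miR-241-3p with 54 reads) were highest in this library. All 3 reached 10 reads in this library alone, so the filter fixed that outcome and it lends no support. The 3 are also too few to decide. miR-240-5p of the same lists had 0 reads in it against 3 and 8 in the others, and let-7-5p and lin-4-5p together had 2 reads. Embryos older than 500 min and a biological difference between these embryos were not tested.

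Hairpins with almost no reads lay late on some chromosomes. Among the hairpins placed on WBcel235, counts had a rank correlation of -0.335 with position within chromosomes (-0.313 on I, -0.325 on II, -0.638 on III, -0.200 on IV, 0.145 on V and -0.417 on X), a measure that treats clustered hairpins as separate. By order along each chromosome, 60 of the 116 earlier hairpins had 100 or more reads, against 34 of the 119 later ones. Some late hairpins had many reads, such as mir-44 on II at 11890023 with 476034 and mir-52 on IV at 14034008 with 47049. The hypothesis that reads and annotation were placed on different genome builds stayed open: the correlation of -0.335 describes the pattern that prompted it and lends it no support, and the build is not given in the sources used here. A real difference in expression along chromosomes was not tested.

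Neighbouring hairpins followed similar courses. Among 91 hairpins, 43 pairs on the same strand within 10 kb had a mean correlation over the stages of 0.634, against 0.00590 for random pairs (one-sided permutation p 1e-04, the smallest the 10000 resamples can give), and the 22 pairs outside the mir-35 cluster had 0.489. Shared transcripts could account for this, as could reads that related neighbours share, which was not tested. Of the 43 pairs, 4 had a negative correlation: mir-2 with mir-71 (-0.813), mir-73 with mir-75 (-0.748), mir-51 with mir-53 (-0.246) and mir-42 with mir-43 (-0.0474).

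The hypothesis that the less abundant arm of a hairpin peaks earlier than the other stayed undecided: its weighted mean time was later by 6.405 min on average (SD 62.5, 36 hairpins, 14 earlier, permutation p 0.543), and over the 12 hairpins whose minor arm had 1000 or more reads the difference was -11.5 min (p 0.628).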
